A study of Mus musculus with 6 samples.

How the data were processed

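RNA was measured in 6 samples of mouse cerebellum from a conditional Ptch1 (Ptc) medulloblastoma model. The tumours arise in the granule neuron lineage, where Cre recombinase under the Math1 promoter deletes Ptch1, the receptor that restrains Hedgehog signalling. Per the labels, 3 samples came from mice given vehicle for 3 weeks and 3 from mice given saridegib, an inhibitor of the Hedgehog pathway protein Smoothened, for 6 weeks. Total RNA was copied into biotin-labelled cRNA and hybridised to Illumina bead arrays, per the labels' protocols. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples, which could be partly technical.

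The values analysed were the authors' deposited log2 signals for 45281 probes on 6 arrays. Their scale was read from the values: every array had the same median (7.48), minimum (6.85) and maximum (15.09), so the arrays had been quantile normalised against each other. Most probes lay close to a floor, which may mean that background had not been subtracted, though the values alone cannot show this. The log base is not stated. The range fits base 2, or a variance-stabilising transform close to it at high signal, and differences are therefore given in log2 units. Because of the floor, differences of dim genes are compressed. The software and settings behind the values are not given in the sources used here. Another table held 6 columns whose names match no sample label, and it was not used.

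The design had assumed non-normalised signals with detection p-values. With neither usable, the normalised values were kept as they are, as the design foresaw, and dim probes were filtered against a background estimated from the values. The background mode was 7.35 and its SD, taken from the lower side, was 0.117. A probe was kept when it lay over 7.54 (the mode plus 1.645 SD) on at least 3 of the 6 arrays, which kept 20130 probes. This filter was set after seeing the distribution of values and before any test. Every array had between 44.1% and 44.2% of probes over that level. A gene is called not well above background where all its probes lay at or under 7.54 on every array of a group. The number of arrays limits the precision.

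Probe names came from a table of the array platform, updated through Entrez gene IDs with a RefSeq gene table of the mouse assembly GRCm38.p6. A single gene symbol was listed for 34885 probes, several for 18 and none for 10378. Of the probes with 1 symbol, 34807 were matched by ID and 78 kept the platform's symbol. No build is given for the probes, so no coordinates are reported, and the assembly was used only for names and gene order. For gene lists and the values of named genes, each of 10822 genes was represented by its kept probe with the highest mean, and the number of genes past the threshold is given both over any probe and over these probes. Of 4157 genes with several kept probes, 1742 had probes that differed in the sign of the change.

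Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), saridegib minus vehicle, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. No covariate or block was used. Genes whose adjusted p lies under that threshold are described as having risen or fallen. Gene lists (37 in all: Hedgehog targets, G1/S phase, G2/M phase, 18 other processes and 16 cell types) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Fry tests whether a list's genes move, on balance, in 1 direction, without comparing them with other genes. The lists hold 869 genes, of which 784 had a named probe and 609 were measured. An exact 2-sided permutation test of each list's mean per array cannot go below p = 0.10 with 3 arrays against 3.

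Lists, tests and the rule for named genes were fixed before the data were examined. The rule takes every Hedgehog target, the 10 genes with the largest rise and the 10 with the largest fall past the threshold whose groups do not overlap, up to 4 members of each other list with the smallest p, and further genes chosen in advance, such as Smo, Abcb1a and Gfap. Genes named outside it are said to be. Alternatives fixed beforehand were no filter, a strict filter (over 7.62 on all 6 arrays, in place of a detection p), the replicate number as a block, labelled sex as a covariate, trended and robust moderation, array weights, each sample left out in turn, another probe per gene, other list tests and other thresholds. Normexp background correction of the unlogged values (offsets 50 and 16) and centring on the median of kept probes were added after seeing the data.

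The probe test was tested on simulated data built from the 20130 probes. With 200 probes changed in each of 5 simulations, it recovered 35.3% of changes of 0.5 on the log2 scale, 83.1% of changes of 1 and 98.9% of changes of 2, with 27 false calls in total. In 5 simulations of the list test over 10822 genes, a list shifted by 0.4 was called in 5 and no unshifted list was called. Genes were simulated independently of each other, so this does not test calls that arise from genes varying together across arrays.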

Results

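The data are 6 arrays of mouse cerebellum from the Ptch1 medulloblastoma model, 3 from vehicle and 3 from saridegib treatment. How much tumour each sample held is not known here. Mice began daily intraperitoneal dosing between postnatal days 21 and 36, with saridegib at 20 mg/kg for 6 weeks or with 5% cyclodextrin vehicle for 3 weeks. Treatment length, and with it age, therefore differs between the groups together with the drug. Across the 20130 kept probes, arrays of the saridegib group correlated at 0.985 to 0.988, vehicle arrays at 0.977, and arrays of different groups at 0.970 to 0.981. No pair of arrays held the same values.

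Xist, the RNA of the inactive X chromosome, and Eif2s3y, a gene of the Y chromosome, were set beside the sex labels. Saridegib replicate 1 is labelled male and had Xist at 7.40, under the background level of 7.54, and Eif2s3y at 9.16. The sample labelled vehicle replicate 2 is labelled female, but had Xist at 7.28 and Eif2s3y at 9.40. The other 4 samples, labelled female, had Xist between 10.43 and 11.76 and Eif2s3y at or under 7.35. The labels of 5 samples thus match their sex-linked probes and that of 1 vehicle sample does not.

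**Figure D1:**
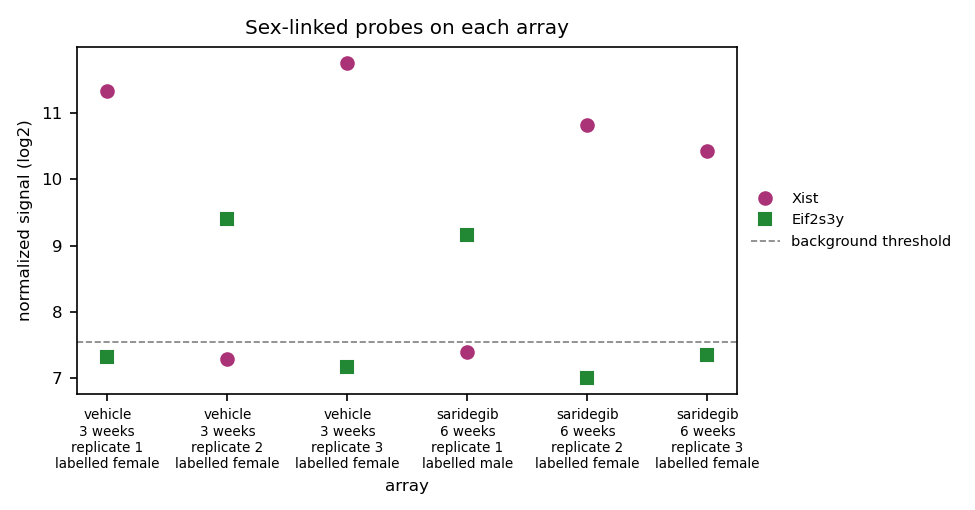
Normalized log2 signal of the Xist and Eif2s3y probes (vertical axis) on each of the 6 arrays (horizontal axis, with the labelled sex), 1 point per array and probe; the dashed line is the background level of 7.54. Xist lies under the line and Eif2s3y above it in saridegib replicate 1, labelled male, and in vehicle replicate 2, labelled female.

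The main comparison asked which genes differed between cerebellum of this model after 6 weeks of saridegib and after 3 weeks of vehicle. Lgals3, which encodes the carbohydrate-binding lectin galectin-3, showed the largest rise, from 9.56 ± 0.95 to 11.79 ± 0.32 (SD, n = 3 each), a log2 difference of 2.23 (SE 0.385, limma adjusted p = 0.0490). Vsnl1, a neuronal calcium sensor, rose by 1.54 (SE 0.206, adjusted p = 0.0288), and Itih3, a hyaluronan-binding extracellular protein, rose by 1.53 (SE 0.112), with the smallest adjusted p of all probes, 0.00333. Rprml, a relative of the cell cycle regulator Reprimo, showed the largest fall, from 10.17 ± 0.67 to 7.998 ± 0.193, a difference of -2.17 (SE 0.275, adjusted p = 0.0258).

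In total, 90 of 20130 probes passed the threshold, 68 higher and 22 lower with saridegib. Counting any probe, they covered 71 named genes, 52 higher and 19 lower, and 14 probes without a gene name; 64 genes passed by the probe with the highest mean, which the gene lists use. For 3459 probes (17.2%) the groups did not overlap, against 10% by chance. The other leading rises were Eno2, the neuronal enolase (1.52), Pvalb, the calcium buffer parvalbumin (1.48), the noncoding RNA Snhg11 (1.43), Gng13, a G protein gamma subunit (1.41), Kndc1 (1.41), Chn2, a GTPase-activating protein for Rac (1.29), and Atp1b1, a subunit of the sodium pump (1.27). Their adjusted p-values lay between 0.0288 and 0.0480. The other leading falls were Adat2, a tRNA adenosine deaminase (-1.09), the nicotinic receptor subunit Chrna3 (-1.07), the glutathione transferase Gsto1 (-0.91), the NMDA receptor subunit Grin3a (-0.85), the homeobox gene En1 (-0.82), Fut10 (-0.78), Dpysl4 (-0.76), Fam126a (-0.73) and Kdelr2 (-0.71). Their adjusted p-values lay between 0.0250 and 0.0480. Dimmer probes of En1 (-0.29), Fam126a (-0.050), Dpysl4 (-0.28 and -0.51), Fut10 (-0.26, -0.53 and -0.12) and Snhg11 (1.21) changed less and did not pass. For each of these 20 genes all 3 saridegib arrays lay outside the vehicle range.

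The count rested on individual arrays: 4 probes passed without saridegib replicate 1, 2 without saridegib replicate 2, 2 without saridegib replicate 3, 58 without vehicle replicate 1 and 266 without the sample labelled vehicle replicate 2. Labelled sex as a covariate also left 4, because it marks saridegib replicate 1 alone. It does not adjust for sex as the probes show it, and no fit with that sex was run. Of 16 alternative fits, including these, Lgals3 passed in 8 (adjusted p 0.0151 to 0.273), Chn2, Atp1b1 and En1 in 7 each, B2m in 9, Rprml in 11, Vsnl1 in 12 and Itih3 in 16 (adjusted p 0.000169 to 0.0394). Oasl2 passed in 7 of 15. Not all of these fits could differ from the main one. Labelled sex repeats the fit without saridegib replicate 1. Centring moved the arrays by almost nothing, as the medians of kept probes were 8.209 to 8.21. Another probe per gene changes nothing for genes with no other kept probe, such as Lgals3, Chn2 and Atp1b1.

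**Figure D2:**
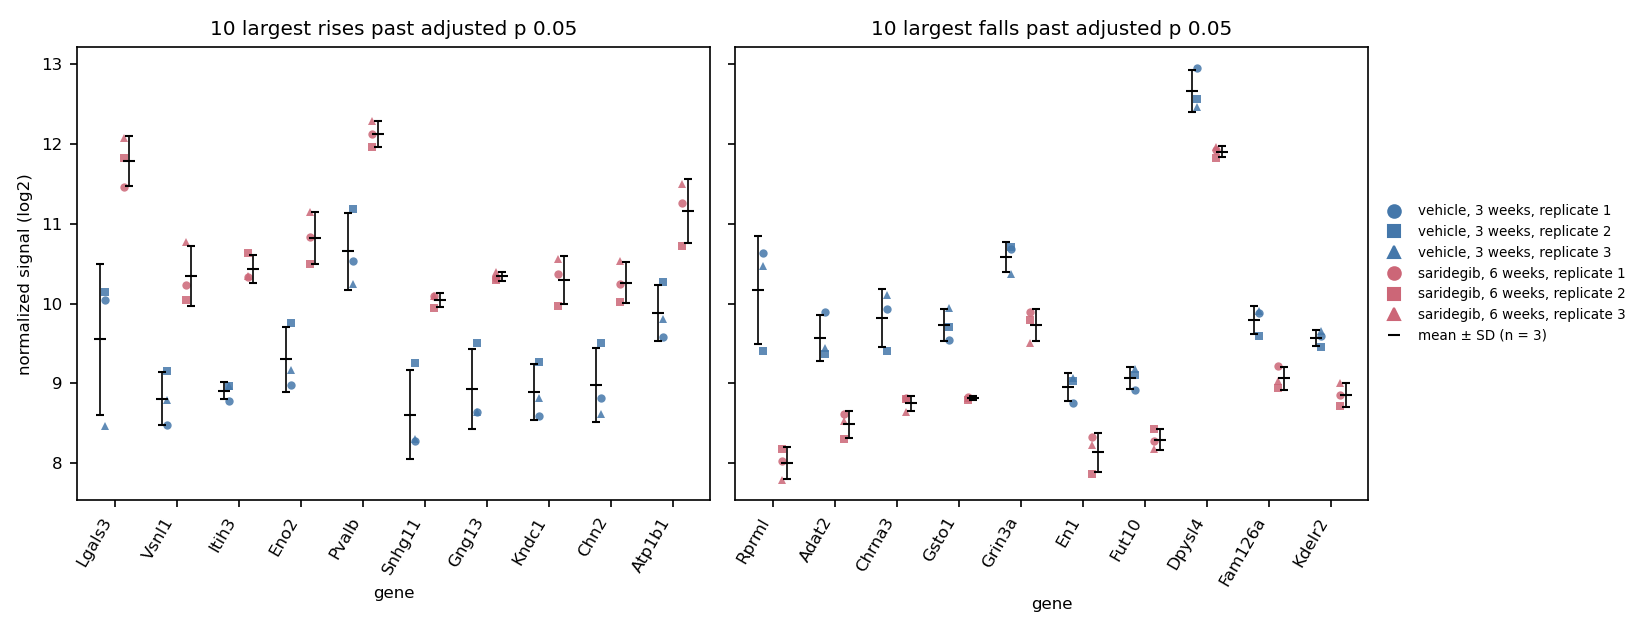
Normalized log2 signal (vertical axis) of the 10 genes with the largest rise and the 10 with the largest fall (horizontal axis) among genes past adjusted p 0.05; points are the 6 arrays, coloured by group and shaped by replicate, and bars are mean ± SD (n = 3). In each gene the 3 saridegib arrays lie outside the range of the 3 vehicle arrays.

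Saridegib inhibits Smoothened, so transcriptional targets of the Hedgehog pathway were examined as a list. None of its 12 measured members rose or fell by limma, and none passed when adjusted over the list alone; 1 was higher and 2 were lower at an unadjusted p under 0.05. The mean log2 difference was -0.069 (SE 0.111, n = 3 each), with a camera adjusted p of 0.412, adjusted p = 0.791 with an estimated correlation, and an exact permutation p of 0.5. Ptch1, both the receptor and a target, was at 10.58 ± 0.14 with vehicle and 10.43 ± 0.35 with saridegib, a difference of -0.15 (SE 0.164, adjusted p = 0.792), and a second, dimmer Ptch1 probe differed by -0.28 (unadjusted p = 0.0314, adjusted p = 0.331). Where its probes lie relative to the deleted part of the gene is not known here, so its level checks nothing about the knockout.

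Gli2, a transcription factor of the pathway, differed by 0.03 (adjusted p = 0.968), the cyclin genes Ccnd1 and Ccnd2 by -0.14 (adjusted p = 0.809) and 0.31 (adjusted p = 0.516), and Sfrp1, a secreted Wnt antagonist, by -0.42 (adjusted p = 0.353). A second Sfrp1 probe differed by -0.87 (adjusted p = 0.130). Other Ccnd2 probes differed by 0.43 (limma adjusted p = 0.253) and 0.38 (limma adjusted p = 0.353). Other Ccnd1 probes differed by -0.08 and -0.099. Rab34 differed by -0.34 (adjusted p = 0.250), Bmi1 by -0.19, Nkx2-2 by -0.11, Hhip by -0.062, Igf2 by -0.049 and Cdk6 by -0.037. Hhatl was not well above background in any vehicle array, with a measured mean of 7.36 against 7.69 with saridegib (adjusted p = 0.183). Gli1, Mycn, Fst, Foxf1 and Tnfrsf11a were left out by the filter; Gli1, with means of 7.27 and 7.28, and Mycn, with 7.28 and 7.31, were not well above background in either group. With 1 sample left out the list's mean was 0.001 without vehicle replicate 1, -0.101 without the sample labelled vehicle replicate 2, -0.106 without vehicle replicate 3, -0.040 without saridegib replicate 2, -0.013 without saridegib replicate 3 and -0.155 without saridegib replicate 1, the only such fit with a camera adjusted p under 0.05 (0.0409, and 0.718 with an estimated correlation).

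**Figure D3:**
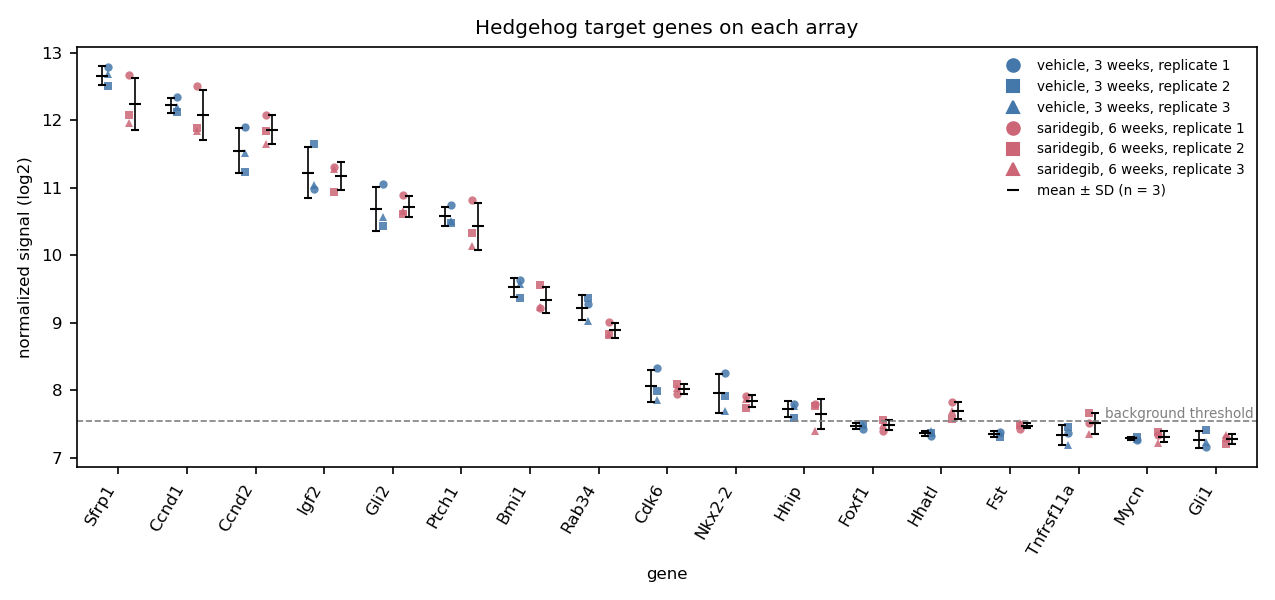
Normalized log2 signal (vertical axis) of the Hedgehog target genes with a probe (horizontal axis) on each of the 6 arrays; points are coloured by group and shaped by replicate, bars are mean ± SD (n = 3), and the dashed line is the background level of 7.54. Ptch1 and Gli2 overlap between the groups, and Gli1 and Mycn lie under the line on all arrays.

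Pathway components other than targets were examined beside them. None of the 12 measured members rose or fell, and 2 were higher when adjusted over the list alone; the mean was 0.049 (camera adjusted p = 0.627), with 0.020 without the sample labelled vehicle replicate 2, 0.024 without saridegib replicate 1, 0.030 without vehicle replicate 1 and 0.096 without vehicle replicate 3. Smo, the target of the drug, differed by 0.44 (SE 0.112, adjusted p = 0.137) on its brightest probe and by 0.047, 0.054 and 0.076 on 3 others. Among other members Gli3 differed by 0.50 (adjusted p = 0.126), Prkaca by -0.23 and the inhibitor Sufu by 0.062 (adjusted p = 0.896). The 22 measured genes of the primary cilium, the organelle in which Smo acts, had a mean of 0.004 (camera adjusted p = 0.940) that ran from -0.015 without the sample labelled vehicle replicate 2 to 0.036 without vehicle replicate 1, with Tulp3 at 0.26 and Ift74 at -0.23.

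Proliferation lists had negative means no larger than their SE, and their groups overlapped (exact permutation p = 0.6 for each). Of 38 genes of the G1 and S phases, 31 had negative differences and the mean was -0.124 (SE 0.124; camera adjusted p = 0.00405; adjusted p = 0.725 with an estimated correlation). Among them the replication factor Gins2 differed by -0.34 and the histone chaperone subunit Chaf1b by -0.33, and the helicase gene Mcm7 by -0.25 on its brightest probe (adjusted p = 0.643), while another Mcm7 probe, singled out after its values were seen, fell by 0.62 (adjusted p = 0.0356). Of 41 genes of the G2 and M phases, 34 had negative differences and the mean was -0.090 (SE 0.109; camera adjusted p = 0.0230; adjusted p = 0.725 with an estimated correlation). Its member with the smallest p, the condensin gene Ncapd2, differed by 0.23 (adjusted p = 0.327), Hmgb2 by -0.28 and the mitotic kinase gene Aurkb by -0.27. By the probe with the highest mean, each list had 0 genes past the threshold by limma over all probes and 0 adjusted over the list alone. Without vehicle replicate 1 the means were -0.007 and 0.005, and without the sample labelled vehicle replicate 2 they were -0.200 and -0.179. The G2/M call was also lost without saridegib replicate 2 (mean -0.072, camera adjusted p = 0.0823).

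Markers of mature cerebellar neurons were higher with saridegib. Among 17 mature granule neuron genes, 2 rose (Vsnl1 and Chn2) and 10 were higher when adjusted over the list alone, with a mean of 0.61 (SE 0.224; camera adjusted p = 6.1e-10; adjusted p = 0.345 with an estimated correlation). Calb2, encoding calretinin, differed by 1.61 (adjusted p = 0.0532) on its brightest probe and rose by 1.17 (adjusted p = 0.0311) on another. Among other members the synaptic organiser Cbln1 differed by 0.74 (adjusted p = 0.0647). Among 14 Purkinje cell genes 1 rose (Gng13) and 6 were higher over the list alone, with a mean of 0.41 (SE 0.075; camera adjusted p = 0.000793; adjusted p = 0.303 with an estimated correlation; fry adjusted p = 0.0339, the only list fry called). With 1 sample left out, fry called 3 lists without the sample labelled vehicle replicate 2, the Purkinje cell list among them. It called 0 in each other such fit. Pcp2, a Purkinje cell protein, differed by 1.39 (adjusted p = 0.0659) and the nuclear receptor Rora by 0.55.

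Among 9 genes of cerebellar interneurons 2 rose, Pvalb and Gad1, which makes the transmitter GABA (1.09, adjusted p = 0.0311), and 7 were higher adjusted over the list alone. The list's mean was 0.58 (SE 0.123; camera adjusted p = 4e-07; adjusted p = 0.303 with an estimated correlation). The vesicular GABA transporter Slc32a1 differed by 1.04 (adjusted p = 0.0532). None of 22 synapse genes rose, 3 were higher adjusted over the list alone, and the mean was 0.29 (camera adjusted p = 0.000102; adjusted p = 0.671 with an estimated correlation), with the vesicle protein Syt1 at 1.14 (adjusted p = 0.110), and at 0.71 and 0.15 on dimmer probes. Without vehicle replicate 1 the synapse list was at 0.13 (camera adjusted p = 0.0675). For genes of earlier granule cell stages no call was made: 17 progenitor genes had a mean of -0.023 (camera adjusted p = 0.733; 2 lower adjusted over the list alone, with -0.063 without the sample labelled vehicle replicate 2 and 0.010 without saridegib replicate 1) and 17 genes of migrating immature neurons a mean of 0.010 (camera adjusted p = 0.940; -0.119 without vehicle replicate 1 and 0.108 without the sample labelled vehicle replicate 2), with no member past the threshold on its brightest probe. Another probe of Nfib, on the immature neuron list and singled out after its values were seen, fell by 0.72 (adjusted p = 0.0288). Barhl1, a transcription factor of granule neuron progenitors, differed by -0.64 (adjusted p = 0.110), and Atoh1 was not well above background in either group.

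The astrocyte and oligodendrocyte lists were called higher with the preset correlation. The oligodendrocyte precursor list was called lower, although its groups overlapped (exact permutation p = 0.4). Among 21 astrocyte and Bergmann glia genes 1 rose, Gja1, the gap junction gene of connexin 43 (1.06, adjusted p = 0.0236), and 4 were higher adjusted over the list alone, with a mean of 0.37 (SE 0.133; camera adjusted p = 1.85e-06; adjusted p = 0.345 with an estimated correlation). Gfap, the astrocyte filament gene, differed by 1.13 (adjusted p = 0.0929) and by 0.46 on a dimmer probe. None of 17 oligodendrocyte genes rose, 6 were higher adjusted over the list alone, and the mean was 0.43 (SE 0.169; camera adjusted p = 9.63e-07; adjusted p = 0.420 with an estimated correlation), with the myelin gene Mag at 1.03 (adjusted p = 0.0832). The myelin gene Mbp was at 1.18 (adjusted p = 0.179) on its brightest probe and at 0.65, 0.14 and -0.066 on 3 others. The 13 oligodendrocyte precursor genes had a mean of -0.221 (SE 0.200; camera adjusted p = 0.0115; adjusted p = 0.700 with an estimated correlation); none fell, 1 was lower adjusted over the list alone, and C1ql1 differed by -0.62 (adjusted p = 0.0691). The precursor list was at -0.040 without vehicle replicate 1 (camera adjusted p = 0.671) and at -0.195 without saridegib replicate 1 (camera adjusted p = 0.0578), and at -0.377 without vehicle replicate 3.

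Antigen presentation and interferon response genes showed the smallest camera p of the 37 lists. B2m, the light chain of class I molecules, rose by 0.95 (adjusted p = 0.0477), Oasl2 rose by 0.56 (adjusted p = 0.0480), and 14 of 21 members were higher adjusted over the list alone. The mean was 0.47 (SE 0.124; camera adjusted p = 3.63e-12; adjusted p = 0.303 with an estimated correlation), with the class II gene H2-Ab1 at 0.68 (adjusted p = 0.0883). None of 22 microglia and macrophage genes rose and 4 were higher adjusted over the list alone; their mean was 0.28 (SE 0.166; camera adjusted p = 0.000681; adjusted p = 0.671 with an estimated correlation), with the lysozyme genes Lyz1 at 1.23 (adjusted p = 0.0892) and Lyz2 at 1.31 (adjusted p = 0.0929). Without vehicle replicate 3 the microglia and macrophage mean was 0.125 (camera adjusted p = 0.231).

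Among 17 meningeal fibroblast genes the matrix proteoglycan gene Dcn rose (1.22, adjusted p = 0.0311, with 0.53 and adjusted p = 0.169 on a dimmer probe) and 4 were higher adjusted over the list alone, with a mean of 0.31 (camera adjusted p = 0.00990; adjusted p = 0.303 with an estimated correlation). Igfbp5, also on this list, differed by 1.16 (adjusted p = 0.0798) on its brightest probe and rose by 1.16 (adjusted p = 0.0319) on another. Haemoglobin genes were measured on every array: 6 erythrocyte genes had a mean of 0.92 (SE 0.535; camera adjusted p = 0.0230; adjusted p = 0.671 with an estimated correlation), their groups overlapped, and Hba-a1 differed by 1.74 (SE 0.582, adjusted p = 0.250). The 8 ependymal genes had a mean of 0.18 (camera adjusted p = 0.0437; adjusted p = 0.671 with an estimated correlation; 0 rose, 1 was higher adjusted over the list alone). The erythrocyte call was lost without any of vehicle replicates 1 and 2 and saridegib replicates 1 and 2 (means 0.672 to 0.917), and the ependymal call without vehicle replicate 3, saridegib replicate 1 or saridegib replicate 3 (means 0.080 to 0.172). No call was made for 21 endothelial and pericyte genes (mean 0.019, camera adjusted p = 0.473; 1 higher and 1 lower adjusted over the list alone), 4 lymphocyte genes (0.096, 0.340), 6 neutrophil genes (0.38, 0.339) or 10 choroid plexus genes (mean 0.19, median -0.011, camera adjusted p = 0.536). With 1 sample left out, the choroid plexus mean ran from -0.087 without vehicle replicate 3, through 0.041 without saridegib replicate 3 and 0.34 without saridegib replicate 1, to 0.42 without the sample labelled vehicle replicate 2 (camera adjusted p = 0.0369; adjusted p = 0.493 with an estimated correlation). The endothelial mean ran from 0.003 without saridegib replicate 3 to 0.038 without saridegib replicate 2, and the lymphocyte mean was 0.151 without vehicle replicate 3 and 0.064 without the sample labelled vehicle replicate 2. The neutrophil mean was 0.024 without vehicle replicate 3 and 0.58 without the sample labelled vehicle replicate 2. Flt1, an endothelial receptor, differed by 0.46 and Ramp2 by -0.48 (adjusted p = 0.0868).

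Of the remaining lists, 2 were higher. Among 18 glycolysis genes Eno2 rose and 7 were higher adjusted over the list alone, with a mean of 0.27 (camera adjusted p = 0.000357; adjusted p = 0.303 with an estimated correlation); Eno2 is the neuronal form, and Aldoc, at 0.92 (adjusted p = 0.0832), is also on the Purkinje cell and astrocyte lists. None of 11 cholesterol efflux genes rose, 2 were higher adjusted over the list alone, and the mean was 0.21 (camera adjusted p = 0.00321; adjusted p = 0.303 with an estimated correlation), with Scd1 at 0.38. Drug efflux transporters were included because such pumps can export Hedgehog inhibitors. None of 11 measured members rose or fell, or passed adjusted over the list alone (mean 0.070, camera adjusted p = 0.340). The mean was 0.107 without the sample labelled vehicle replicate 2 and 0.043 without vehicle replicate 3. Abcb1a and Abcg2 were not well above background in either group and Abcb1b differed by -0.11 (adjusted p = 0.694).

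The other lists were not called. Camera adjusted p was 0.0522 for 23 ribosomal protein genes (mean -0.097; Rpl30 fell by 0.70, adjusted p = 0.0311, and by 0.28 on a dimmer probe, adjusted p = 0.248), 0.0548 for 18 cholesterol synthesis genes (mean -0.122) and 0.0579 for 10 drug metabolism genes (mean 0.17). These 3 calls rested on which samples were used: without the sample labelled vehicle replicate 2 camera adjusted p was 0.0370, 0.00790 and 0.00790 (adjusted p = 0.419, 0.427 and 0.419 with an estimated correlation). The ribosome mean was -0.051 without saridegib replicate 3 and -0.060 without vehicle replicate 1, and passed without saridegib replicate 1 (-0.125, adjusted p = 0.535 with an estimated correlation) or 2 (-0.115, adjusted p = 0.551 with an estimated correlation). Cholesterol synthesis was at -0.073 without vehicle replicate 3, at -0.076 without saridegib replicate 1 and passed without saridegib replicate 2 (-0.166; adjusted p = 0.702 with an estimated correlation). Drug metabolism was at 0.104 without vehicle replicate 3 and passed without saridegib replicate 3 (0.191; adjusted p = 0.711 with an estimated correlation). Adjusted over the list alone, 2 ribosomal protein genes were lower and 2 drug metabolism genes higher. The 15 Wnt genes had a mean of -0.002 and a median of 0.021 (camera adjusted p = 0.910; 2 higher and 2 lower adjusted over the list alone), with Wnt7a rising by 0.61 (adjusted p = 0.0288), and the mean ran from -0.048 without the sample labelled vehicle replicate 2 to 0.026 without saridegib replicate 3. The 23 genes of PI3K and IGF signalling had a mean of 0.051 and a median of -0.046 (camera adjusted p = 0.712), or a mean of 0.025 without saridegib replicate 1. Igf1r differed by -0.18. Means were -0.095 for 10 Notch genes (camera adjusted p = 0.340; -0.153 without saridegib replicate 1 and -0.057 without saridegib replicate 3), -0.003 for 12 neural stem and tumour-propagating cell genes (0.627; another probe of Cd44, singled out after its values were seen, rose by 0.63), -0.002 for 31 oxidative phosphorylation genes (0.811), 0.015 for 22 p53 and apoptosis genes (0.627, between 0.006 and 0.029 with 1 sample left out), 0.043 for 17 immediate early genes (0.682) and 0.105 for 17 heat shock and stress genes (0.328; 0.021 without the sample labelled vehicle replicate 2 and 0.163 without vehicle replicate 3). The means of the neural stem, oxidative phosphorylation and immediate early lists changed sign with 1 sample left out, and none of these 6 lists was called in any such fit. Adjusted over each list alone, 1 PI3K and IGF, 1 oxidative phosphorylation and 2 heat shock and stress genes were higher and 1 neural stem gene was lower.

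In all, 16 of 37 lists were called with the preset correlation, 13 higher and 3 lower. With an estimated correlation limma's camera called 0, with 6 lists at an unadjusted p under 0.05, and fry called 1. The groups were fully apart in 12 lists, each at an exact permutation p of 0.1, the smallest the design allows. Without vehicle replicate 1 the preset correlation called 11 lists.

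**Figure D4:**
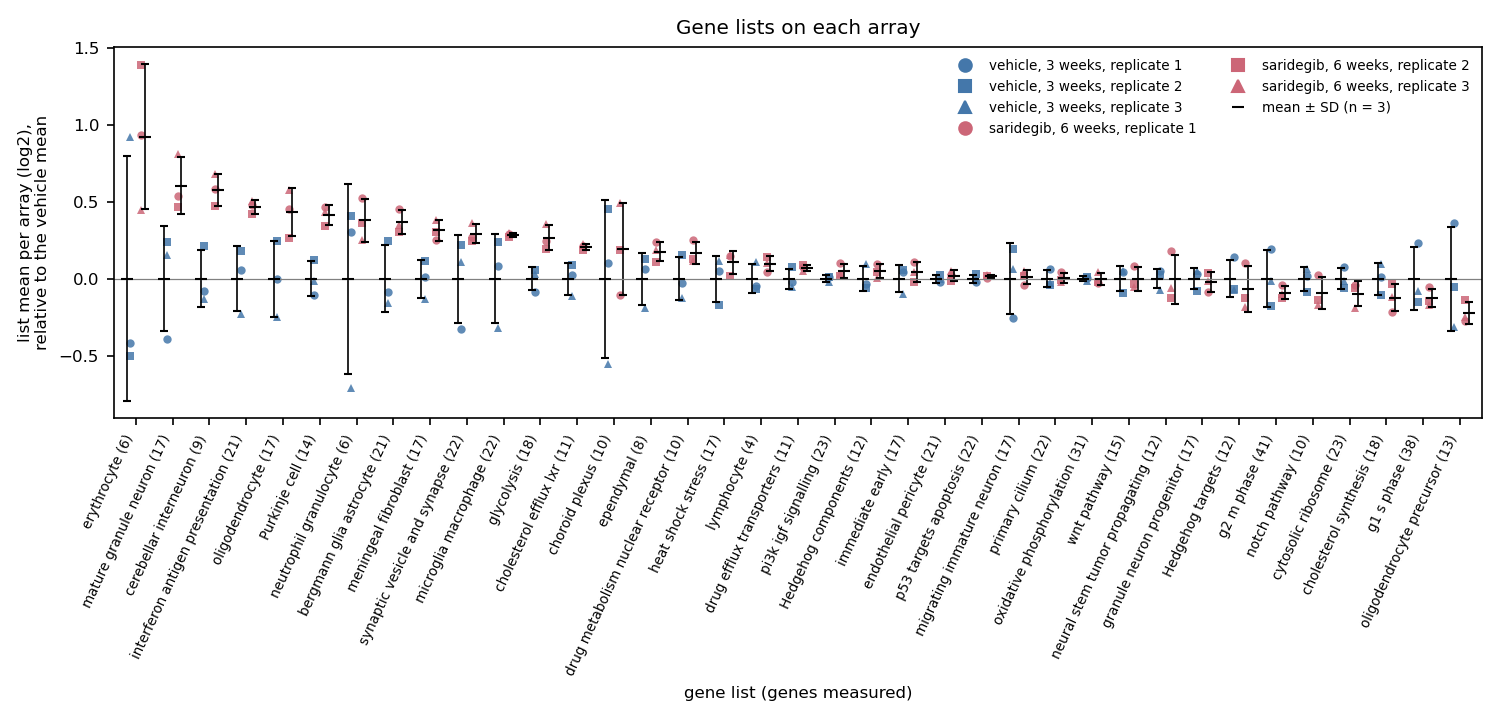
Mean log2 signal of each gene list on each array, relative to the vehicle mean (vertical axis), for the 37 lists (horizontal axis, number of measured genes in parentheses); points are the 6 arrays, coloured by group and shaped by replicate, and bars are mean ± SD (n = 3). The mature granule neuron, interneuron and Purkinje cell lists lie higher on all 3 saridegib arrays than on all 3 vehicle arrays, and the erythrocyte list overlaps between the groups.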

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

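Normexp background correction and centring were chosen after seeing the data. Of the alternatives fixed beforehand, those starting from non-normalised signal, median scaling and slide blocks were not run, because columns could not be given to samples, quantile-normalised values leave median scaling nothing to move, and no slide is named. The 90 probes past the threshold (68 higher, 22 lower) became 94 without a filter, 92 with the strict filter, 121 with array weights and 90 with centring. Trended, robust moderation gave 182 (151 higher), normexp with offset 50 gave 144 (117 higher), and with offset 16 gave 25 (21 higher, 4 lower). Labelled sex as a covariate left 4 (4 higher, 0 lower), the same fit as leaving out saridegib replicate 1. At adjusted p 0.01, 4 passed (4 higher, 0 lower), and 36 had an absolute log2 difference of at least 1 (33 higher, 3 lower). With 1 sample left out, counts ran from 2 to 266, 1 to 218 higher and 0 to 48 lower, and fewer samples are tested there. With the replicate number as a block, 59 passed (39 higher), 43 of them among the 90, and 7 in place of 4 other process lists were called. Deviations of same-numbered samples correlated at 0.05, -0.14 and 0.02, so the numbers were not taken to pair samples. Array weights also called 7 process lists. With an estimated correlation 0 process lists and 0 cell type lists were called, and with fry 0 and 1, against 4 and 10; process lists ran from 3 to 7 with 1 sample left out. The G1/S mean of -0.124 and the G2/M mean of -0.090 kept those values but lost their calls with both tests, and ran from -0.200 to -0.007 and from -0.179 to 0.005 with 1 sample left out. The sign of the G2/M list turned without vehicle replicate 1 (0.005). The Hedgehog target mean passed with labelled sex as a covariate (-0.155; adjusted p = 0.718 with an estimated correlation) and ran from -0.155 to 0.001 with 1 sample left out. Of 431 alternative values of the 27 named genes past the threshold, 261 stayed past it and 170 did not. Some of the 261 come from fits that hardly differ from the main one, such as centring. Sign changes of values past no threshold in either fit were not counted as reversals. Where not given, the cause was not tested. Signal near background limits what the probes of genes such as Gli1, Mycn and Abcg2 can show. Whether such a gene is weakly expressed or its probe reports poorly was not tested.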

Other observations

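The genes in this paragraph lie outside the rule for named genes and were chosen after their values were seen. Gadd45g, a stress-response gene, rose by 1.17 (SE 0.108, limma adjusted p = 0.00639) and was higher in 3 of 3 saridegib arrays than in any vehicle array. Thy1, a surface glycoprotein of neurons, rose by 1.23, the small heat shock protein gene Hspb8 by 1.14, the phospholipid-binding annexin gene Anxa5 by 1.02, the zinc transporter gene Slc39a12 by 1.02, the chemokine gene Cxcl12 by 0.87 and the sodium pump subunit gene Atp1b2 by 0.84. The class I gene H2-T23 rose by 0.82 and the extracellular matrix genes Prelp and Aebp1 by 0.93 and 0.74. Among falls, Socs2, a feedback inhibitor of cytokine signalling, changed by -0.71 and Crip2 by -0.71. Ttr, an abundant choroid plexus gene, ranged from 7.65 to 13.71 between vehicle arrays and from 8.06 to 13.18 between saridegib arrays.

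The tests of vehicle replicate 2 and of the neuronal and glial markers were chosen after the patterns were seen, except that of treatment length; the splits of samples and the tests of neighbouring genes were set before their results were seen, although the wording of the criterion for splits and some decision rules were revised afterwards. The sample labelled vehicle replicate 2 had the sex-linked pattern of a male. A mixture of RNA from a female and a male is argued against by its Xist signal of 7.28, under background. A wrong sex label remains a candidate explanation, since its Eif2s3y signal lay 0.24 above that of the sample labelled male. Whether a sample of the saridegib group was placed there cannot be told apart from an unusual vehicle sample: over the 200 probes ranked without it, its median position between the vehicle mean (0) and the saridegib mean (1) was 0.47 (quartiles 0.32 and 0.64), against 0.13 and 0.15 for the other vehicle samples and 0.74, 0.74 and 1.01 for the saridegib samples held out in the same way. Over the kept probes, the sample labelled vehicle replicate 2 had a mean correlation of 0.9788 with the saridegib arrays and 0.977 with the other vehicle arrays. For vehicle replicates 1 and 3 these were 0.9718 and 0.9737 with the saridegib arrays, and 0.9767 and 0.9771 with the other vehicle arrays. An exchange of samples within the series would not remove the sex mismatch. Saridegib replicate 1 also had male sex-linked probes, and it alone is labelled male. No biological explanation was tested for the sample labelled vehicle replicate 2.

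The 5 lists of mature granule neurons, Purkinje cells, interneurons, astrocytes and oligodendrocytes were called higher with saridegib with the preset correlation and not with an estimated one (adjusted p = 0.303 to 0.420). With all 6 samples fry called the Purkinje cell list alone, a call that was lost in most fits with 1 sample left out. The oligodendrocyte precursor list was called lower (-0.221, adjusted p = 0.700 with an estimated correlation), although its groups overlapped. A lower share of tumour cells that raises every other cell type alike stays open. The mean of the 5 lists called higher exceeded that of the endothelial and pericyte list by 0.46 (SE 0.10). The 5 lists were compared because they had been called higher, so this difference cannot decide. Differentiation of granule neurons, as the whole account or as a part of the rise, stays open too. The other 4 lists, which share no gene with the granule neuron list, had a mean rise of 0.45 (SE 0.12). They were taken because they had been called higher, so this mean restates the pattern and cannot decide. The test was also changed 2 times after its results were seen. A version on adjusted p with an estimated correlation, smallest 0.303, decided neither way. More non-tumour cerebellum in the saridegib samples may contribute and stays open: the granule neuron progenitor list, whose genes tumour cells also express, differed by -0.023 (SE 0.055), which decides neither way (it replaced a test, the smallest ratio of a list's mean to its SE, 2.56, that only restated the pattern), and treatment length and age cannot be told apart from the drug, as 0 treatments were sampled at more than 1 length.

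The strain background is mixed, so haplotypes that differ between the groups could place called genes near each other. Among the 64 genes past the threshold by the probe with the highest mean, 9 pairs lay within 50 genes of each other on a chromosome, against a mean of 5.12 in 2000 random draws (permutation p = 0.074), which leaves this open. Examples, of which Nme7 and Rida lie outside the rule for named genes and were chosen after their values were seen, are Nme7 and Atp1b1, both of which rose, and Rpl30 and Rida, 3 genes apart, of which Rpl30 fell and Rida rose by 0.90. A test on genes with 2 clear levels across arrays was void, with 3 such genes, 0 neighbouring pairs and a permutation p of 1.

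The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05. For probes, 1 split, the real one, gave as many as 90, and the highest other gave 1. Every split called gene lists with the preset correlation: the real one called 16, and the others 7, 8, 7, 16, 14, 10, 8, 5 and 2, so 2 splits gave as many as 16. The other split with 16 exchanges vehicle replicate 2 and saridegib replicate 1, the samples with male sex-linked probes.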
